A study of Mus musculus with 6 samples.

How the data were processed

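Total RNA from pancreatic tumour cells of 6 mouse samples, 3 wild-type for Msi1 and 3 Msi1 -/-, was labelled with biotin from 6 ug of RNA and hybridised to Affymetrix mouse arrays, per the labels' protocols. The intensity values were deposited by the authors as 1 table of probe set values. Per the submitters' processing notes they were made with GCRMA, a method that corrects background by probe sequence, normalizes quantiles across arrays and summarises probes, with no version or settings given. The deposited intensities are linear: the lowest value per array lay between 51.2 and 59.9 and the highest between 19332 and 20365. Whether the values were rescaled after GCRMA is not given in the sources used here, and scanner files were not used here. Compression at the low end by such background correction, or by a later rescaling, would shrink differences of dim transcripts.

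Groups and replicate numbers were taken from the labels. The files held 45101 probe sets; 64 control probe sets were left out and 45037 tested. A platform annotation table named the probe sets: 34945 had 1 gene symbol, 932 had several and 9160 were not listed with a gene, and probe sets with several symbols were not named. Symbols were updated through Entrez identifiers with a RefSeq gene table of the mouse assembly GRCm38.p6, with 34754 probe set entries matched, and no coordinates are given. The 34945 probe sets stood for 18193 genes.

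Values were analysed as log2(intensity + 1), so differences understate changes of dim transcripts. The design planned before the data were examined assumed log2 values and a filter on a mean of at least 4. Because the values are linear this filter removed 0 probe sets, as did a filter at 3, and the one at 6 removed 14; filters at 7 and 8 were therefore added after seeing the data. A linear model with genotype as the only term was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend = TRUE), and p-values were adjusted by the Benjamini-Hochberg method at 0.05. Exact two-sided permutation tests covered all 20 assignments of 3 and 3 arrays, whose smallest p is 0.1. SD is over arrays; SE of a single probe set is limma's moderated standard error, with a median of 0.0815 over all probe sets.

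Gene lists were fixed before the data were examined: 33 lists of pathways or functions and 17 lists of cell type markers, with 774 of 855 entries measured; list members outside these were not analysed here. Each gene was represented by its probe set of highest mean. The 49 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry as alternatives. Fry asks whether the genes of a list move, on balance, in one direction, without comparing them with other genes. A list score is the mean log2 value of its members in an array minus their mean over the 6 arrays. Members were also adjusted over the list alone.

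The rule for named genes was fixed before the data were examined. It takes every probe set of Msi1 and Msi2, all Musashi targets of the list, up to 4 members of each list past the threshold by smallest unadjusted p, and the 12 genes with the largest positive and the 12 with the largest negative difference among probe sets with 1 symbol, no overlap between the groups and an adjusted p under 0.05. As none had such an adjusted p, the 24 were filled, as the rule says, from probe sets with an unadjusted p under 0.01. Where several probe sets of a gene qualified, the one with the highest mean was used, so a gene can have another value as a list member. Ptf1a, Bhlha15, Ighm and the genes named only in the other observations were chosen after their values were seen.

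The fit was tested on simulated data for this comparison, with 45037 probe sets and 200 changed probe sets in each of 5 runs. Means were real, variances were limma's moderated ones and noise was independent between probe sets. The fit recovered 94% of changes of log2 1 and 99.6% of those of log2 2, with 10.2 false calls per run. Changed probe sets were drawn at random from all those tested, whose SE had a median of 0.0815 and a 95th percentile of 0.217. Many genes named below had larger SEs, such as 0.44 for Reg3a, so these shares do not apply to them. Camera was also tested in 5 runs, on 1 row per gene with the real means and noise of the same SD for every gene. It called 0 unshifted lists per run and found the shifted list in all 5 runs. This noise was not correlated between genes, so these runs do not show how often camera calls lists in the real arrays.

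Alternatives changed one choice at a time: the filter, the prior variance, normalization between arrays (quantile, median centring, cyclic loess), array weights, the replicate number as a block, each array left out in turn, the threshold, probe sets averaged per gene, a pseudocount of 16, the probe set taken per gene, and the list test. Background was taken as the 95th percentile, per array, of 79 probe sets for olfactory, vomeronasal and trace amine receptors. The sources used here gave no scan date or hybridisation batch, so batches could not be tested.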

Results

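Gene expression was measured in tumour cells from the pancreas of C57BL/6 mice at 11 weeks of age. The mice carried engineered tumour alleles, among them a conditional p53 allele with a Cre driver at the Ptf1a locus. In 3 samples Msi1 was intact, called wild-type here although the tumour alleles were present. The other 3 samples had the genotype Msi1 -/- and are called Msi1-null. Msi1 encodes Musashi 1, an RNA-binding protein of neural and epithelial progenitor cells that controls the translation of its target mRNAs. Each of the 6 RNA samples was hybridised to 1 Affymetrix mouse array with 45101 probe sets. The number of arrays limits the precision. Median deposited intensity lay between 159.2 and 164.3 in the 6 arrays. The labels do not state clearly that each sample came from a separate animal, so p-values measure the spread between these samples.

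The comparison asked which transcripts differ between pancreatic tumours with and without Msi1. The 3 probe sets for Msi1 were dim in both genotypes and did not separate them. The brightest, 1452287_at, had a mean intensity of 184 ± 63.6 (SD, n = 3) in wild-type and 146 ± 21.0 (SD, n = 3) in Msi1-null arrays, a log2 difference of -0.29 ± 0.22 (SE; exact two-sided permutation p = 0.4). Probe sets 1421409_at and 1444306_at differed by 0.09 ± 0.07 and -0.07 ± 0.08 (SE). The wild-type mean of 1452287_at rested on wild-type replicate 3, at 257, and without this array the log2 difference was -0.02. In wild-type arrays 1 of the 9 Msi1 values lay above the 95th percentile of 79 probe sets for olfactory and related receptors, used as array background, and in Msi1-null arrays likewise 1 of 9. Where the probe sets lie relative to the deleted part of Msi1 was not known here, so they do not check the genotype labels. Msi2, the related Musashi gene, gave a clear signal at 1436818_a_at, with 793 ± 27.7 in wild-type and 766 ± 137 in Msi1-null arrays (SD, n = 3), a log2 difference of -0.07 ± 0.15 (SE). Across the 8 Msi2 probe sets the log2 differences ran from -0.15 to 0.06.

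**Figure D1:**
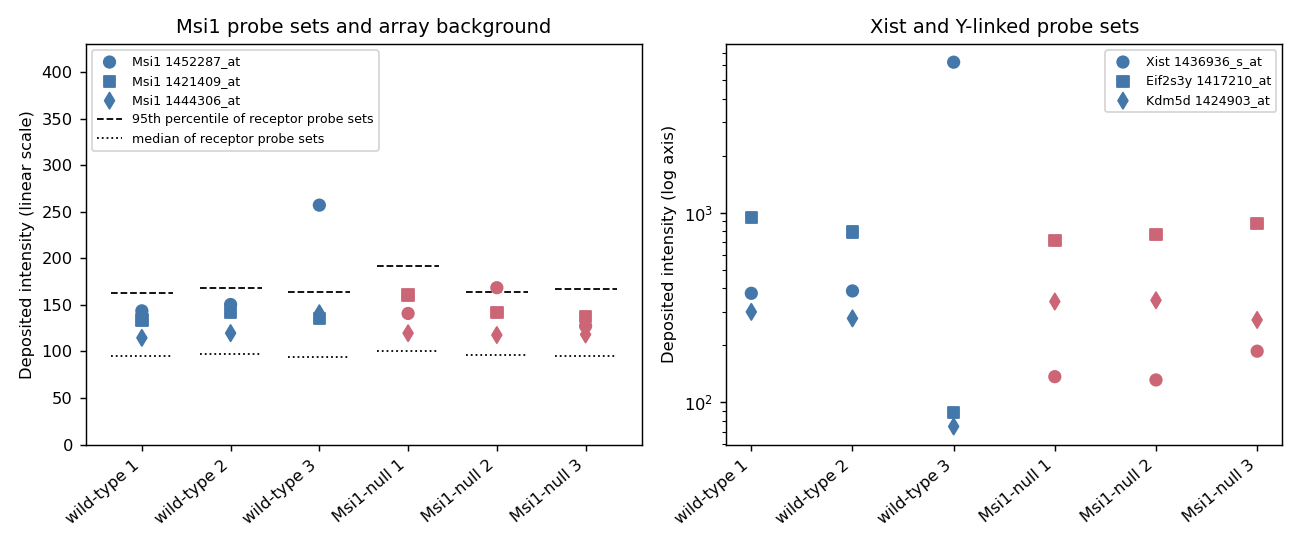
Deposited intensity of the 3 Msi1 probe sets on a linear axis (left) and of Xist, Eif2s3y and Kdm5d probe sets on a log axis (right) in each of the 6 arrays, wild-type in blue and Msi1-null in red, with the median (dotted) and 95th percentile (dashed) of receptor probe sets marked per array on the left. One wild-type and one Msi1-null Msi1 value exceed the dashed line, and wild-type replicate 3 has Xist at 6226 and Eif2s3y at 88.2.

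The arrays also differed in sex-linked transcripts. Xist, transcribed from the inactive X chromosome, read 6226 in wild-type replicate 3 at its brightest probe set, 376 and 387 in wild-type replicates 1 and 2 and between 131 and 186 in Msi1-null arrays. The Y-linked gene Eif2s3y read 88.2 in wild-type replicate 3 and between 716 and 944 in the others. One wild-type array thus had a female pattern and the other 5 arrays a male one, and the labels do not give the sex of the animals.

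No transcript passed the threshold between the genotypes. Among single genes with an unadjusted p under 0.01, a limit that leaves out Xist (-2.69 ± 0.99, SE, and -1.35 without wild-type replicate 3), the largest differences without overlap were lower values in Msi1-null arrays for Chil3, a chitinase-like protein of alternatively activated macrophages, and for the pancreatic genes Cela3b, an elastase of acinar cells, Klk1, tissue kallikrein, and Reg3a, a secreted lectin. The largest higher values were for Fcrls, an Fc receptor-like gene of macrophages and microglia, Tm4sf1, a tetraspanin-like surface protein, Ccl12, a monocyte chemokine, and Ube2c, a ubiquitin-conjugating enzyme of mitotic exit. Of 45037 probe sets tested with limma, 0 had an adjusted p below 0.05, and the smallest adjusted p was 0.9997 (limma, Benjamini-Hochberg). At an unadjusted p under 0.05 there were 1355 probe sets, 659 higher and 696 lower in Msi1-null arrays, against 2252 that chance alone gives. That count was 2723 without Msi1-null replicate 1 and 886 without wild-type replicate 1. The groups did not overlap at 3510 probe sets, 7.79% of those tested, against 10% by chance.

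The genes described next were named by size of difference, and their values are not calls. Chil3 averaged 8945 ± 6379.95 in wild-type and 1055 ± 834 in Msi1-null arrays (SD, n = 3), a log2 difference of -3.13 ± 0.64 (SE). Cela3b differed by -2.07 ± 0.59, Klk1 by -1.90 ± 0.43 and Reg3a by -1.57 ± 0.44 on the log2 scale (SE). Reg3d, a paralog of Reg3a, differed by -1.01 ± 0.29 and Wfdc21, a secreted protein of the whey acidic protein family, by -1.06 ± 0.20 (SE). Smaller negative differences were seen for Arg1, the arginase of tumour macrophages (-0.80 ± 0.23), and Uchl1, a neuronal ubiquitin hydrolase (-0.76 ± 0.16). Those of Mcemp1, a myeloid membrane protein, and Cd177, a neutrophil surface protein, were -0.75 ± 0.21 and -0.65 ± 0.17. Lrrc15, a membrane protein of activated fibroblasts, and Igfbp2, a binding protein for insulin-like growth factors, differed by -0.70 ± 0.16 and -0.68 ± 0.19.

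Among the genes higher in Msi1-null arrays, Fcrls averaged 685 ± 240.1 against 246 ± 84.1 (SD, n = 3), a log2 difference of 1.48 ± 0.30 (SE). Tm4sf1 differed by 1.17 ± 0.31, Ccl12 by 1.14 ± 0.30 and Ube2c by 1.03 ± 0.29 (SE). Further cell division genes were among the 12 named: Cenpa, the centromeric histone (0.64 ± 0.18), Ccnb2 and Ccna2, cyclins of mitosis and of S and G2 phase (0.63 ± 0.14 and 0.61 ± 0.17), Kif20a, a mitotic kinesin (0.57 ± 0.14), Pclaf, a PCNA-binding protein (0.55 ± 0.15), and Racgap1, a regulator of cytokinesis (0.51 ± 0.15). Trav9d-3, a T cell receptor segment, and Rtp4, an interferon-induced protein, differed by 0.67 ± 0.17 and 0.64 ± 0.18. The rule took only genes without overlap between the groups, so leaving out 1 array could not change the sign of these 24 genes. In the 6 fits that left out 1 array each, 1 gene moved by over 1.5 times, Arg1, to -0.53 without Msi1-null replicate 2. With probe sets averaged per gene another 6 did: Klk1 was -0.94, Tm4sf1 0.68, Trav9d-3 0.38, Rtp4 0.33, Racgap1 0.32 and Cenpa 0.24. Other probe sets of 3 of the genes pointed the opposite way: 1 of 5 for Trav9d-3, 1 of 3 for Cenpa and 1 of 4 for Klk1.

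**Figure D2:**
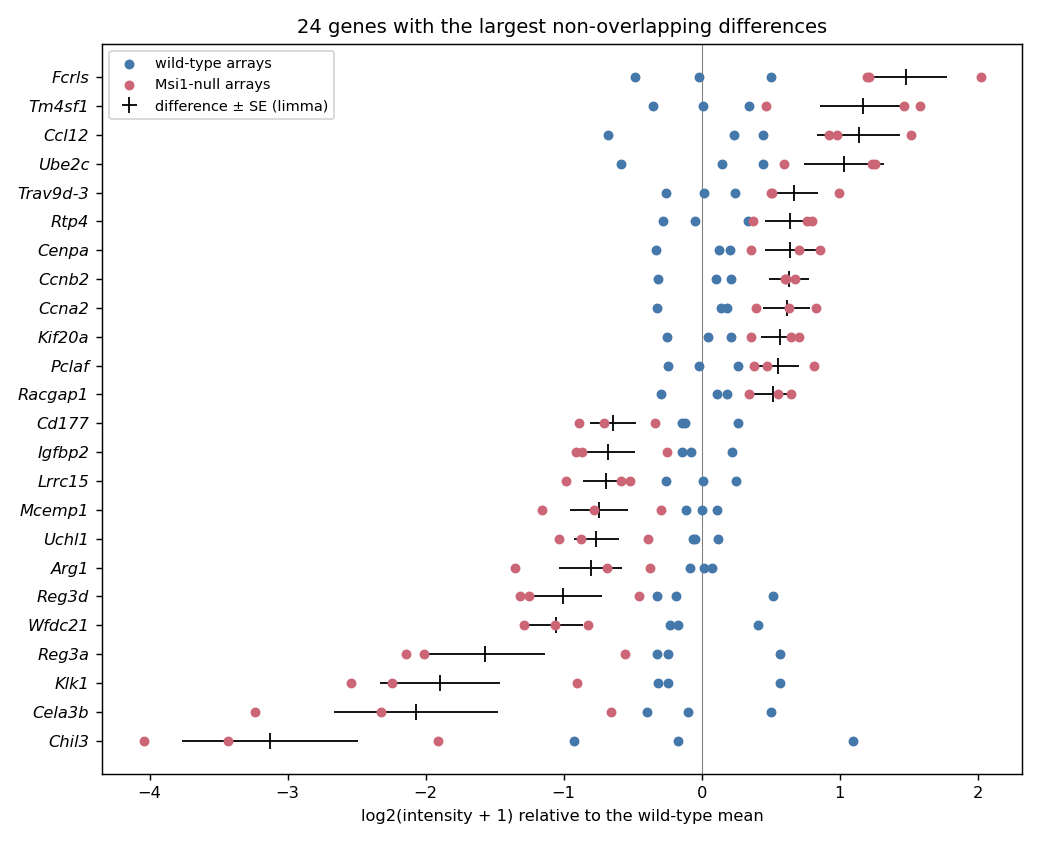
The 24 named genes, with the log2(intensity + 1) of each array relative to the wild-type mean on the horizontal axis; blue points are wild-type arrays, red points Msi1-null arrays, and the black line is the limma difference ± SE. Chil3 has the longest distance, -3.13, and Msi1-null replicate 3 lies closest to the wild-type arrays for Cela3b, Klk1 and Reg3a.

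Genes of G2 and M phase were higher on average in Msi1-null arrays, as a set. All 23 measured members had higher means, with a mean log2 difference of 0.57, and none of the Msi1-null array scores overlapped the wild-type scores (exact two-sided permutation p = 0.1, the smallest that 3 against 3 arrays allow). Examples are Ccnb2 (0.63 ± 0.14), Kif20a (0.57 ± 0.14), Ube2c (1.03 ± 0.29) and the mitotic kinase Plk1 (0.55 ± 0.17, SE). The list passed in camera with a preset correlation (adjusted p = 2.1e-24) but not with the correlation estimated from the data (p = 0.0613, adjusted p = 0.749 with an estimated correlation). Adjusted over the list alone, 16 of the 23 members passed 0.05, and 0 passed over all probe sets. Wild-type replicate 1 had the lowest score of the 6 arrays, and without it the mean log2 difference was 0.37.

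S phase genes, which encode replication proteins, had higher means for 22 of 23 members, with a mean log2 difference of 0.21. Tk1, Prim1, Rrm2 and Pcna differed by 0.44 ± 0.19, 0.40 ± 0.18, 0.71 ± 0.35 and 0.19 ± 0.10 (SE). The list passed in camera (adjusted p = 8.04e-07) and not otherwise (adjusted p = 0.749 with an estimated correlation). Adjusted over the list alone, 0 members passed, and without wild-type replicate 1 the mean was 0.10.

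Interferon response genes, induced in cells by type I and type II interferon, were higher on average in Msi1-null arrays for 22 of 22 members. Their mean log2 difference was 0.29. Mx1, an antiviral GTPase, differed by 0.33 ± 0.06, Oasl1 by 0.43 ± 0.12, Ifit1 by 0.40 ± 0.11 and the chemokine gene Cxcl9 by 0.66 ± 0.20 (SE). Scores of the 3 Msi1-null arrays lay above all 3 wild-type scores (exact permutation p = 0.1). The list passed in camera (adjusted p = 2.26e-14) but not when the correlation was estimated (p = 0.0474, adjusted p = 0.749 with an estimated correlation). Adjusted over the list alone, 1 member passed, Mx1.

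Antigen presentation genes gave higher means for 15 of 15 members, with a mean log2 difference of 0.40. Tapbp and Tap1, which serve peptide loading of class I molecules, differed by 0.29 ± 0.09 and 0.48 ± 0.17 (SE). Psmb9 of the immunoproteasome differed by 0.49 ± 0.23 and Ciita, the class II transactivator, by 0.52 ± 0.26 (SE). With probe sets averaged per gene Tap1 differed by 0.11 and Ciita by 0.27. Without wild-type replicate 1 Tap1, Psmb9 and Ciita differed by 0.31, 0.29 and 0.20. Camera gave an adjusted p of 2.98e-07 (adjusted p = 0.749 with an estimated correlation), and 0 members passed adjusted over the list alone. Wild-type replicate 1 again had the lowest score, -0.70, and the groups overlapped (exact permutation p = 0.4). The mean was 0.15 without this array, 0.15 with array weights and 0.25 without Msi1-null replicate 1.

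Lymphocyte markers were also higher on average. T and NK cell markers had higher means for 15 of 16 members, with a mean log2 difference of 0.26. The groups did not overlap (exact permutation p = 0.1), but the lowest Msi1-null score, -0.005, was close to the highest wild-type score, -0.02. Cd2, Klrd1, Cd247 and Cd3g differed by 0.45 ± 0.18, 0.39 ± 0.16, 0.29 ± 0.12 and 0.50 ± 0.21 (SE). These genes were dim, with wild-type means of 129, 123, 111 and 153 and Msi1-null means of 178, 162, 136 and 221. The array background, the 95th percentile of receptor probe sets, lay between 163 and 192. For B and plasma cells 11 of 13 markers had higher means, with a mean log2 difference of 0.27. Cr2, Blk, Fcer2a and Cd22 differed by 0.34 ± 0.13, 0.29 ± 0.14, 0.39 ± 0.23 and 0.43 ± 0.27 (SE). Wild-type means of Cr2, Blk and Fcer2a, at 153, 138 and 150, lay below that background, while Cd22, at 442, lay above it. Camera adjusted p-values were 1.26e-06 for T and NK cells (adjusted p = 0.749 with an estimated correlation) and 0.00161 for B and plasma cells (adjusted p = 0.814 with an estimated correlation). Neither list had a member past 0.05 adjusted over the list alone. Without wild-type replicate 1 the means were 0.16 for T and NK cells and 0.12 for B and plasma cells. Without Msi1-null replicate 2 they were 0.17 and -0.02, and the B cell list passed in neither of these fits nor with the filter at 8, while its mean was 0.51 without Msi1-null replicate 1. With the filter at 8, 3 T and NK cell markers were left, too few to test.

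Acinar cell markers, the digestive enzymes of the exocrine pancreas, were lower on average in Msi1-null arrays. Of 18 measured markers 17 had lower means, and the mean log2 difference was -1.10 ± 0.51 (SE over arrays). At the brightest probe set of each gene, Cela3b differed by -1.98 ± 0.59, Pnliprp1, a lipase relative, by -1.68 ± 0.51, and the carboxypeptidases Cpb1 and Cpa1 by -1.91 ± 0.61 and -1.49 ± 0.48 (SE). The acinar transcription factor genes Ptf1a and Bhlha15, both dim, differed by -0.02 ± 0.17 and 0.05 ± 0.14 (SE). Camera gave an adjusted p of 5.64e-12 (adjusted p = 0.749 with an estimated correlation), and adjusted over the list alone 0 members passed, with a smallest value of 0.0575. Msi1-null replicate 3 scored 0.35, within the wild-type range of 0.27 to 0.94, while the other Msi1-null arrays scored -1.22 and -0.78 (exact permutation p = 0.2). The 3' to 5' signal ratio of the Gapdh control probe sets, a sign of RNA quality, was also lowest in Msi1-null replicate 1, at 1.38, and highest in wild-type replicate 2, at 1.86, as the acinar and Reg family scores were. Its means were 1.53 ± 0.128 in Msi1-null and 1.69 ± 0.156 in wild-type arrays (SD, n = 3, exact permutation p = 0.3).

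The Reg family, secreted proteins of acinar and inflamed gastrointestinal tissue, followed a similar order of arrays. Means were lower for 6 of 7 members, with a mean log2 difference of -0.63. Reg3a (-1.57 ± 0.44) and Reg3d (-1.01 ± 0.29) passed 0.05 adjusted over the list alone, 2 of 7 in all. Reg2 (-1.44 ± 0.51) and Reg4 (0.13 ± 0.09) did not pass. Reg4 was dim, with means of 111 in wild-type and 121 in Msi1-null arrays, below the array background. Camera gave an adjusted p of 0.0095 (adjusted p = 0.749 with an estimated correlation), which was lost without Msi1-null replicate 1 (0.285) or wild-type replicate 2 (0.21). Without Msi1-null replicate 2 Reg2 was -0.88 and Reg4 0.22, and Reg4 was 0.03 without Msi1-null replicate 3.

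RAS and MAPK output genes, feedback regulators and targets of MAP kinase signalling, had lower means for 15 of 17 members. The mean log2 difference was -0.14, with Spry2 at -0.30 ± 0.15, Ier3 at -0.42 ± 0.23, Epha4 at -0.29 ± 0.16 and Spry1 at -0.31 ± 0.21 (SE). The camera adjusted p was 0.0147 (adjusted p = 0.936 with an estimated correlation), and the call was lost without wild-type replicate 3 (mean -0.01) or Msi1-null replicate 1 (mean -0.03), with array weights and with the filter at 8, while the mean was -0.26 without Msi1-null replicate 3 and -0.22 without wild-type replicate 1. Without Msi1-null replicate 2 Ier3 differed by -0.16, and without Msi1-null replicate 1 Spry2 and Epha4 by -0.18 and -0.15. Epithelial junction genes had lower means for 16 of 20 members and a mean log2 difference of -0.12. Esrp1, an epithelial splicing factor, differed by -0.48 ± 0.19, Marveld2 by -0.22 ± 0.09, Grhl2 by -0.17 ± 0.10 and Cldn4 by -0.63 ± 0.38 (SE). The camera adjusted p was 0.0298 (adjusted p = 0.975 with an estimated correlation), and the call was lost without Msi1-null replicate 1 (mean -0.01), wild-type replicate 1 (-0.08) or wild-type replicate 3 (-0.11), and also with the filters at 7 and 8, with array weights (-0.01) and with probe sets averaged per gene, while the mean was -0.24 without Msi1-null replicate 3. Cldn4 differed by -0.14 without Msi1-null replicate 2, and Grhl2 by -0.02 with probe sets averaged per gene. In both lists 0 members passed adjusted over the list alone.

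Another 4 lists passed in camera with small or array-dependent differences. Oxidative phosphorylation genes had higher means for 16 of 23 members, with a mean log2 difference of 0.07 and no overlap between the groups (exact permutation p = 0.1). Uqcrc2, Atp5b, Cox6c and Cycs differed by 0.22 ± 0.10, 0.17 ± 0.09, 0.13 ± 0.07 and 0.31 ± 0.16 (SE). Genes of the unfolded protein response had higher means for 16 of 19 members and a mean log2 difference of 0.10. Sec61b, Pdia4, Pdia6 and Hsp90b1, which act in the endoplasmic reticulum, differed by 0.19 ± 0.09, 0.25 ± 0.12, 0.28 ± 0.14 and 0.21 ± 0.12 (SE). Endothelial markers had higher means for 13 of 16 members, with a mean log2 difference of 0.15. Pecam1, Tek, Emcn and Plvap differed by 0.27 ± 0.11, 0.17 ± 0.09, 0.42 ± 0.25 and 0.32 ± 0.19 (SE). Adipocyte markers had lower means for 9 of 10 members, with a mean log2 difference of -0.25. Ucp1, Retn, Adipoq and Pnpla2 differed by -0.11 ± 0.06, -0.33 ± 0.20, -0.70 ± 0.54 and -0.24 ± 0.19 (SE). Ucp1 was dim, with means of 128 in wild-type and 119 in Msi1-null arrays, below the array background. The adipocyte mean was 0.03 without wild-type replicate 2 and -0.43 without wild-type replicate 1. The endothelial mean was 0.05 without wild-type replicate 1, 0.04 without Msi1-null replicate 1 and 0.26 without either wild-type replicate 2 or Msi1-null replicate 2. Without Msi1-null replicate 2 the oxidative phosphorylation mean was 0.04. The unfolded protein response mean was 0.04 without that array, 0.05 without wild-type replicate 1 and 0.16 without Msi1-null replicate 1. Camera adjusted p-values were 0.0367 for oxidative phosphorylation (adjusted p = 0.749 with an estimated correlation) and 0.00974 for the unfolded protein response (adjusted p = 0.786 with an estimated correlation). They were 0.0095 for endothelial cells (adjusted p = 0.975 with an estimated correlation) and 0.0367 for adipocytes (adjusted p = 0.814 with an estimated correlation). In these 4 lists 0 members passed adjusted over the list alone, and each list lost its call in 2 to 4 of the 6 fits that left out 1 array. With all arrays the calls were also lost for oxidative phosphorylation under quantile and cyclic loess normalization, for endothelial cells with array weights (mean 0.04), and for adipocytes with the filters at 7 and 8 and without the variance trend.

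In all, 14 of 49 lists passed in camera with the preset correlation, 9 higher and 5 lower in Msi1-null arrays. With an estimated correlation 0 lists passed (smallest adjusted p 0.749, with 1 list at an unadjusted p under 0.05), and with fry 0 passed (smallest adjusted p 0.848, with 2 lists at an unadjusted p under 0.05). Array scores separated the genotypes in 6 lists, 12.2% of those tested, against 10% by chance. Of the 89 genes followed through the alternatives, 54 moved by over 1.5 times or changed sign in at least 1 of them, 45 when 1 array was left out and 24 when probe sets were averaged per gene.

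**Figure D3:**
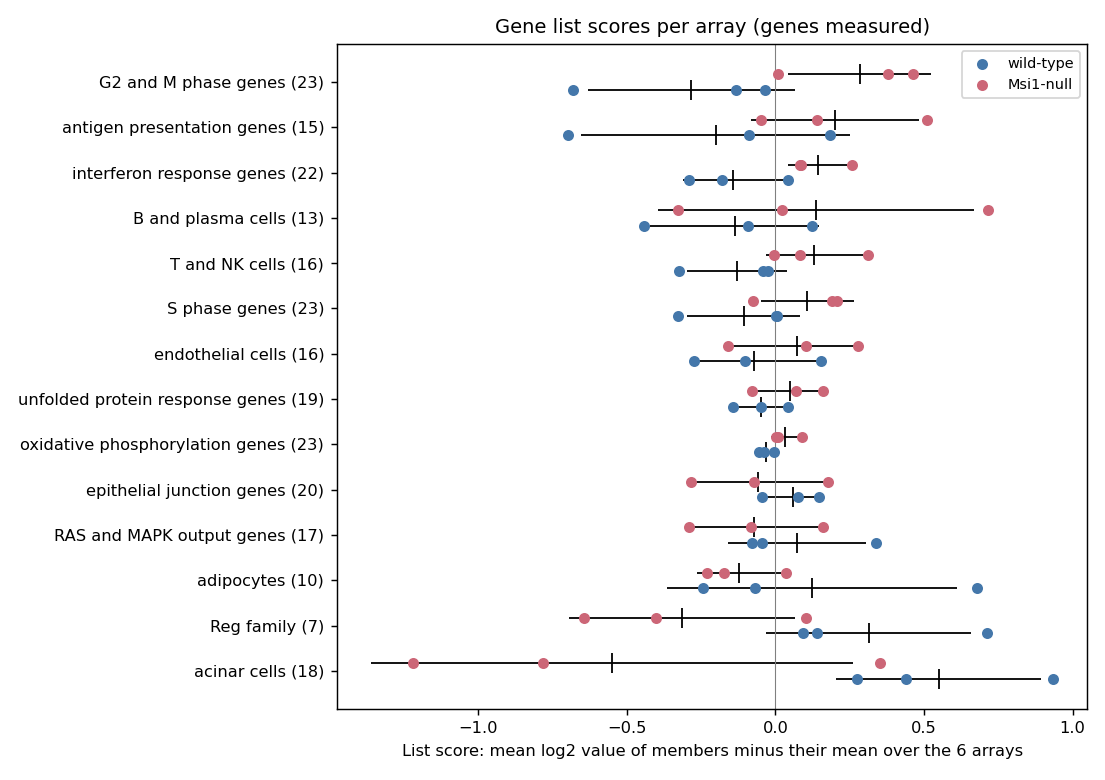
Scores per array for the 14 lists past the camera threshold with the preset correlation: the horizontal axis is the mean log2 value of the members minus their mean over the 6 arrays, with wild-type arrays in blue, Msi1-null arrays in red, and black marks for each group's mean ± SD. G2 and M phase scores do not overlap between the groups, while for acinar cells Msi1-null replicate 3, at 0.35, lies among the wild-type arrays.

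Transcripts known from the literature as Musashi targets showed no call. The list mean was -0.13, with 9 of 14 members lower, and the list did not pass (camera adjusted p = 0.0925, adjusted p = 0.786 with an estimated correlation). Some of these genes may have been chosen by the study itself, so the list is not independent evidence of a direction. No expected direction was set per member, so the list mean would miss changes in opposite directions. The arrays measure mRNA, so control of translation by Musashi 1 would not show in them directly. Hmga2, a chromatin protein, differed by -0.55 ± 0.34, Cdkn1a, the p21 cell cycle inhibitor, by -0.43 ± 0.26, Smad3, a TGF-beta signal transducer, by -0.31 ± 0.16 and Numb, an inhibitor of Notch, by -0.18 ± 0.11 (SE). Tgfbr1, Aff4, Ikzf2 and Tspan3 differed by -0.20 ± 0.21, -0.18 ± 0.15, -0.15 ± 0.20 and -0.11 ± 0.17. Met, the receptor of hepatocyte growth factor, differed by -0.04 ± 0.21, Myc by 0.01 ± 0.18, Ccnd1 by 0.17 ± 0.19 and Jag1 by 0.07 ± 0.31. Hoxa9 and Robo3 differed by 0.02 ± 0.09 and 0.02 ± 0.07. Both were dim, with wild-type means of 173 and 125 and Msi1-null means of 175 and 126. The array background lay between 163 and 192, so these values say little about change. Adjusted over the list alone, 0 members passed. The list passed without wild-type replicate 1 (camera adjusted p = 0.0446), wild-type replicate 2 (0.048) or Msi1-null replicate 3 (0.00528). Its mean was -0.22 without Msi1-null replicate 3. It was -0.08 both without Msi1-null replicate 2 and without wild-type replicate 3, where the list did not pass (camera adjusted p = 0.291 and 0.64). Hmga2 ran from -0.95 without Msi1-null replicate 3 to -0.31 without Msi1-null replicate 1, Smad3 was -0.16 without the latter array, and Cdkn1a was -0.12 without Msi1-null replicate 2. Met and Ikzf2 turned positive without Msi1-null replicate 1, at 0.21 and 0.07.

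The remaining 35 lists, with the Musashi targets among them, did not pass in camera, and their mean log2 differences lay between -0.13 and 0.12. Stem and progenitor genes, such as those that mark self-renewing tumour cells, had a mean log2 difference of -0.05 with 12 of 24 members lower. Mesenchymal transition genes averaged -0.04, ductal markers 0.09, fibroblast markers 0.04 and macrophage markers 0.07. These 3 marker means depended on single arrays. Ductal markers were 0.31 without Msi1-null replicate 1, where they passed (camera adjusted p = 0.00088), and -0.04 without Msi1-null replicate 2. Fibroblast markers were -0.17 and 0.21 in these fits and passed in the second (0.0036), and macrophage markers were -0.12 and 0.23 and passed in both (0.0103 and 0.000265). The 28 neighbours of Msi1 on its chromosome averaged 0.03. With 1 array left out the stem and progenitor mean ran from -0.09 to 0.02 and the mesenchymal mean from -0.10 to 0.04. The mean of the neighbours ran from 0.01 to 0.06. In 10 of the 35 lists the mean, the median and the camera direction did not share a sign, among them mesenchymal transition, extracellular matrix and TGF-beta target genes.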

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

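The filters at 7 and 8 were chosen after seeing the data; all other settings were planned. Under each of the 22 settings of the fit, the count of probe sets past the threshold was 0, in either direction, except that leaving out arrays gave from 0 to 1 probe sets changed and from 0 to 1 higher. The 1 was a probe set of Ighm (1.89 at an adjusted p of 0.0426 in limma without Msi1-null replicate 1); of the others with a mean above 1000, 1 was at 1.90 and 5 between 0.01 and 0.17, none past the threshold. The Msi1 difference at its brightest probe set lay between -0.44 and -0.02 and passed nowhere, and it had no value under the filter at 8, which removed it. The count of lists past the threshold moved from 14 to 9 with the filter at 8, where 4 calls were lost and the T and NK cell list, with 3 members left, was not tested, to 0 with an estimated correlation and to 0 with fry, both of which allow for the correlation between genes of a list. It lay between 12 and 16 under the other settings with all arrays and between 14 and 18 with 1 array left out, of which 8 to 13 were among the 14. With the replicate number as a block (replicate block), 0 probe sets and 16 lists passed, the 14 among them, and 2120 probe sets had an unadjusted p under 0.05 against 1355. Deviations of same-numbered arrays from their group means correlated at 0.17, -0.09 and 0.28. Those of arrays with different numbers ran from -0.26 to 0.06. The labels do not say what the numbers mark, so pairing was neither used in the main fit nor excluded. The planned filters at 3 and 4 and no filter gave identical tests and say nothing about stability. The list tests were not run with the robust prior or with the log2 threshold of 1. A change of sign by less than 1 SE, with neither value past the threshold, was not counted as reversed. By this rule 1927 of 1929 alternative values for 89 followed genes counted as unchanged. Small differences among them, such as those of Jag1 and Myc, did change sign. Without 1 array, Ikzf2 ranged from -0.33 to 0.0701 and Met from -0.21 to 0.21. For the 49 lists, 1021 of 1120 alternative results counted as unchanged, 61 lost the call, 33 gained it and 5 reversed. The reversed lists were, over the fits without 1 array, gastric and mucin genes (-0.30 to 0.49), epithelial junction genes (-0.24 to -0.00679, where the camera direction turned), extracellular matrix genes (-0.25 to 0.15) and macrophages (-0.12 to 0.23), and, with the filter at 7, liver cells (-0.30). The first 4 turned without Msi1-null replicate 1 or 2; the cause was not tested. Signal over background limits the dim transcripts, Msi1 among them.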

Other observations

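Some tests of explanations below were chosen after the result was seen. They are those on splits for single probe sets, on wild-type replicate 3 for Msi1 and on chance for the acinar list. All tests of explanations for the G2 and M list were also chosen then. The fits without 1 array were planned, but their use and bounds in these tests were not. Epithelial gene lists differed widely between the Msi1-null tumours. Gastric and mucin genes of pancreatic neoplasia scored -0.94 in Msi1-null replicate 1 and 0.64 in Msi1-null replicate 2, with a group difference of 0.01. Gkn1, a gastric mucosa protein, read 350.1 and 5474 in these arrays, and Agr2, a mucin-folding enzyme, 357 and 2279. Intestinal epithelial markers scored -0.47, -0.26 and 0.74 in Msi1-null replicates 1, 2 and 3, and Cdh17, an intestinal cadherin, read 720, 344 and 1755.

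Stromal lists were high in Msi1-null replicate 1 and low in replicate 2, opposite to the gastric and mucin genes. Extracellular matrix genes scored 0.30 in Msi1-null replicate 1 and -0.49 in replicate 2, fibroblast markers 0.44 and -0.32, and macrophage markers 0.43 and -0.28. Mrc1, a macrophage receptor, read 4971 and 1474 in them. Ltf, lactoferrin, read 9504 in Msi1-null replicate 2 and between 1035 and 1506 in the other 5 arrays. Ighm, the IgM heavy chain, read 493 in Msi1-null replicate 1 at the probe set that passed without that array, 4754 and 4401 in the other Msi1-null arrays and between 1147 and 1313 in wild-type arrays; its log2 difference was 0.82 ± 0.79 (SE) with all arrays. Of the 11 Ighm probe sets 1 other was alike (0.88), while the 5 others with a mean above 1000 lay between -0.35 and -0.20. The lowest correlation between 2 arrays, 0.975, was that of Msi1-null replicates 1 and 2. The highest, 0.9932, joined wild-type replicate 3 to Msi1-null replicate 3, and wild-type replicates 2 and 3 were about as close, at 0.9929.

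Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real split gave 0 probe sets past the threshold, and the highest of the others gave 3. For lists in camera the real split gave 14 and the others between 14 and 23, so the count was no higher for genotype than for any other split. The split of wild-type replicates 1 and 2 with Msi1-null replicate 1 against the rest gave 4610 probe sets at an unadjusted p under 0.05 and 3 past the threshold, against 1355 and 0 for genotype; whether the samples share a structure other than genotype was not tested.

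Msi1 probe sets were not clearly lower in Msi1-null arrays. A candidate explanation is that Msi1 signal lies near background: 1 of 9 wild-type values exceeded the 95th percentile of receptor probe sets, as did 1 of 9 Msi1-null values. The difference at the brightest probe set rested on wild-type replicate 3, since without it the log2 difference was -0.02381. Few Msi1-expressing cells in a tumour, or probe sets that lie outside the deleted part, remain open and were not tested.

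Acinar markers were lower in 2 of the 3 Msi1-null arrays. Less acinar tissue in those preparations may account for it: another acinar list, written without sight of its values, had a mean log2 difference of -0.4927 with 13 of 18 members lower (72.2%). This missed both bounds set beforehand, narrowly only for the mean, so it does not settle the question. Such a list also cannot tell less acinar tissue from lower expression in acinar cells. Chance differences between tumours cannot be told apart from genotype, because the exact permutation p was 0.2 in a design that cannot go below 0.1. RNA quality, whose Gapdh ratio had its extremes in the same arrays, and slower loss of acinar cells in wild-type tumours, a biological difference tied to Msi1, stay open and were not tested.

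G2 and M phase genes were higher in Msi1-null arrays. Dilution by acinar RNA in wild-type preparations would need the score to fall by 0.515 per unit of acinar score. Within genotypes the slope was 0.2996 ± 0.2177 (SE, 3 degrees of freedom), above the slope needed. That needed slope was taken as exact, although it is a ratio of 2 uncertain group differences. At equal acinar score the genotype difference was 0.896 ± 0.326 (SE), too imprecise with 3 degrees of freedom to tell from no difference. The fit with all arrays thus does not exclude dilution. The slope stayed positive with any 1 array left out, but these fits had only 2 degrees of freedom. Most were too imprecise to separate it from the slope needed, for example 0.208 ± 0.143 against -0.296 without wild-type replicate 1 (SE). The exception was the fit without wild-type replicate 3 (0.330 ± 0.181, SE, against -0.599). The comparison of slopes thus depended on single arrays and does not settle dilution. Msi1-null replicate 3, with an acinar score of 0.35 inside the wild-type range, had the highest G2 and M score, 0.46. However, the list's excess over the mean of ductal, fibroblast, macrophage and endothelial lists, 0.480 ± 0.269 (SE), was under 2 SE. Against 15 marker lists the excess was 0.542 ± 0.205 (SE), and 0.570 ± 0.312 without wild-type replicate 2. It thus depended on the lists compared and on single arrays. Wild-type replicate 1 alone could contribute, since without it the difference was 0.3668 ± 0.148 (SE), still positive but not 2 SE above the bound of 0.1, and the highest other split had a mean difference of 0.54 against 0.57. A change in proliferation without Msi1 is a hypothesis that these arrays do not settle.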
